A study of Mus musculus with 8 samples.

How the data were processed

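RNA of flow-sorted mouse bone marrow cells (strain C57BL/6J) was measured on 8 Affymetrix arrays, 1 for each of 8 independent RNA preparations. The labels give pools of 4 or 6 mice per preparation. Groups and replicate numbers were taken from the sample titles: KLS cells and MEP cells from transgenic (TG) and wild-type (WT) mice, with 2 arrays per group. The genotype label of the TG arrays names a shortened Hmga2.

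The deposited values are on a log2 scale, with 35556 probe sets per array and a range from 1.71 to 14.0. The scale was read from the values. Affymetrix Expression Console was used, per the submitters' processing notes, which name no version. The summarization, background correction and normalization are not given in the sources used here. Arrays have no read depth, and their number limits the precision.

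Arrays were to be used as deposited if their medians lay within 0.1 of each other, and quantile normalized otherwise. The 8 medians spanned 0.106, so quantile normalization was applied. The platform annotation gave 1 gene symbol for 21789 probe sets, several for 1621 and no entry for 12146. Only probe sets with 1 symbol were used, which leaves out the adult globin genes. Symbols were looked up through the Entrez identifier in a RefSeq table of the GRCm38.p6 assembly, used for names alone. It held the identifier of 21698 probe sets and changed 0 symbols. For the 999 genes with more than 1 probe set, the probe set with the highest mean over all arrays was taken, which left 19938 genes.

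Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with defaults). A mean was fitted for each of the 4 groups over all 8 arrays, with 4 residual and 4.82 prior degrees of freedom. The contrasts were TG minus WT in KLS cells, in MEP cells and averaged over both, the interaction (the genotype change in KLS minus that in MEP cells), and KLS minus MEP averaged over genotypes. Tests were two-sided, adjusted by Benjamini-Hochberg over all genes and called at an adjusted p under 0.05. Errors of log2 changes are limma's standard errors (SE), and those of group means are SD.

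The lists covered HSC and multipotent progenitor, erythroid, globin, megakaryocyte, granulocyte and monocyte, lymphoid, mast cell, basophil and eosinophil, stromal and endothelial, cell cycle, CDK inhibitor, p53 target, JAK-STAT, cytokine receptor, IGF and PI3K-AKT, let-7 and Lin28, interferon response, immediate early and heat shock, Hox, Polycomb, TGF-beta and mesenchymal, mitochondrially encoded and ribosomal protein genes. Of these 22 lists, 21 had at least 3 measured members and were tested. The mitochondrially encoded list had 0 measured members and was not tested. The test was camera from limma with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. It was repeated with an estimated correlation and with fry. Members were also adjusted over the list alone.

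Genes were named by a rule. It takes Hmga2, and for each contrast but the interaction the 10 genes with the largest change in each direction that passed the threshold and whose arrays did not overlap between the sides. Where fewer than 5 passed in a direction, genes with the smallest p in that direction were added up to 5. For the interaction, the 5 genes with the smallest p were taken. Each list and contrast adds up to 4 members past the threshold with the largest change, or the member with the smallest p where none passed. Transcripts known only by a clone or model name were skipped. The lists, this rule, the tests of the contrasts and the alternatives named here were fixed before the data were examined; those chosen later are named as such beside their results.

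The procedure was tested on simulated data with 19938 independent genes, 20 runs and 50 changed genes per fold size. A change of 2 fold was recovered for 52.7% of genes by genotype in KLS cells, 53.3% in MEP cells, 87.2% over both, 7.10% for the interaction and 87.6% between cell types. A change of 3 fold was recovered for 92.5% by genotype in KLS cells, 93.5% in MEP cells and 60.4% for the interaction. Genes of all fold sizes were changed together in each run, which eases the adjusted threshold. A gene that changes alone or with few others faces a stricter one, so these shares do not give its chance of being called. With no change, camera made 2 calls in the 20 runs of 105 list tests. This holds for independent genes only. In the data the estimated correlation ran from -0.04 in the Hox list to 0.51 in the lymphoid list, with 0.33 in the granulocyte and monocyte list. The simulation therefore does not give the rate of false calls for such lists.

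Alternatives were the values as deposited, median centring, leaving out the dimmest 30% of genes, the mean over the probe sets of a gene, an intensity trend, robust variances, array weights, the replicate number as a block, all probe sets singly, an added 2-fold minimum, an adjusted p under 0.10, the arrays of 1 cell type alone, ordinary least squares, and each array left out in turn.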

Results

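Gene expression was measured in KLS and MEP cells of mice carrying a shortened Hmga2 (TG) and of wild-type mice (WT). KLS cells are the c-Kit-positive, lineage-negative, Sca-1-positive marrow fraction that holds stem and multipotent progenitor cells, and MEP cells are megakaryocyte-erythroid progenitors. Each of the 4 groups had 2 arrays. The deposited array medians lay between 6.34 and 6.45 on the log2 scale. Replicates correlated across genes at 0.988 in TG KLS, 0.988 in TG MEP, 0.983 in WT KLS and 0.981 in WT MEP cells. Between the replicates, 122, 111, 223 and 421 genes respectively lay more than 2 fold apart.

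Hmga2 encodes a chromatin-binding high mobility group protein whose transcript is a let-7 target through its 3′ untranslated region. It was measured by 1 probe set (10372796, Entrez gene 15364), and whether that lies in the part kept by the shortened gene is not given in the sources used here. Its log2 level was 7.23 ± 0.17 in TG and 6.98 ± 0.19 in WT KLS cells, and 6.97 ± 0.02 in TG and 6.72 ± 0.03 in WT MEP cells (mean ± SD, n = 2 each). The TG and WT arrays overlapped in KLS and not in MEP cells. Averaged over both cell types the change was 0.25 ± 0.11 (SE, 95% interval 0.0035 to 0.49), and it did not pass limma's threshold over all genes (adjusted p = 0.999). A probe outside the kept part would not check the genotype labels.

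The comparison of KLS with MEP cells shows how the sorted populations differ. Members of the granulocyte and monocyte list were among the genes with the largest differences toward KLS cells. Ctsg, the serine protease cathepsin G, was at 10.67 ± 0.73 in KLS and 7.11 ± 0.58 in MEP cells (SD, n = 4 each), a log2 difference of 3.56 ± 0.34 (SE). Mpo, the myeloperoxidase of neutrophil granules, differed by 3.28 ± 0.35, Ms4a3 by 3.35 ± 0.27 and Elane, neutrophil elastase, by 2.72 ± 0.31. Cd34, a surface antigen of early progenitors, differed by 2.97 ± 0.27, Flt3, a receptor of multipotent progenitors, by 2.55 ± 0.26, and Hlf, a transcription factor of stem cells, by 2.24 ± 0.10 (adjusted p = 0.000123). MEP cells were higher for Scd1, a fatty acid desaturase, at -1.22 ± 0.16, for the red cell blood group protein Rhd at -0.77 ± 0.13, for the transferrin receptor Tfrc at -0.56 ± 0.10 and for the CDK inhibitor Cdkn2c at -0.80 ± 0.15. By limma 319 genes passed the threshold, 240 higher in KLS and 79 higher in MEP cells. With each array centred on its median, 79 were higher in KLS and 44 in MEP cells, and Tfrc and Cdkn2c no longer passed (adjusted p = 0.0643 and 0.0687). As deposited, Cdkn2c did not pass either (adjusted p = 0.0534). Without TG MEP 1, 1 gene passed, Hlf, while Ctsg, Mpo, Elane, Cd34 and Flt3 had adjusted p = 0.0629, Ms4a3 0.0624, Scd1 0.0636, Rhd and Tfrc 0.143 and Cdkn2c 0.130. The number called was 20 without TG MEP 2, 30 without TG KLS 1, 103 without WT MEP 2, 117 without WT KLS 1, 136 without WT KLS 2 and 738 without WT MEP 1, of which 290 were among the 319. Elane (adjusted p = 0.0530) and Scd1 (0.0764) did not pass without TG MEP 2, and Scd1 (0.0556) did not without TG KLS 1. Rhd did not pass without TG KLS 1, TG MEP 2, WT KLS 1 or WT MEP 2 (adjusted p from 0.0858 to 0.142). Tfrc passed without WT MEP 1 alone of the arrays, and Cdkn2c without WT KLS 2 alone, with adjusted p of at least 0.0751 and 0.0614 without each of the others.

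**Figure D1:**
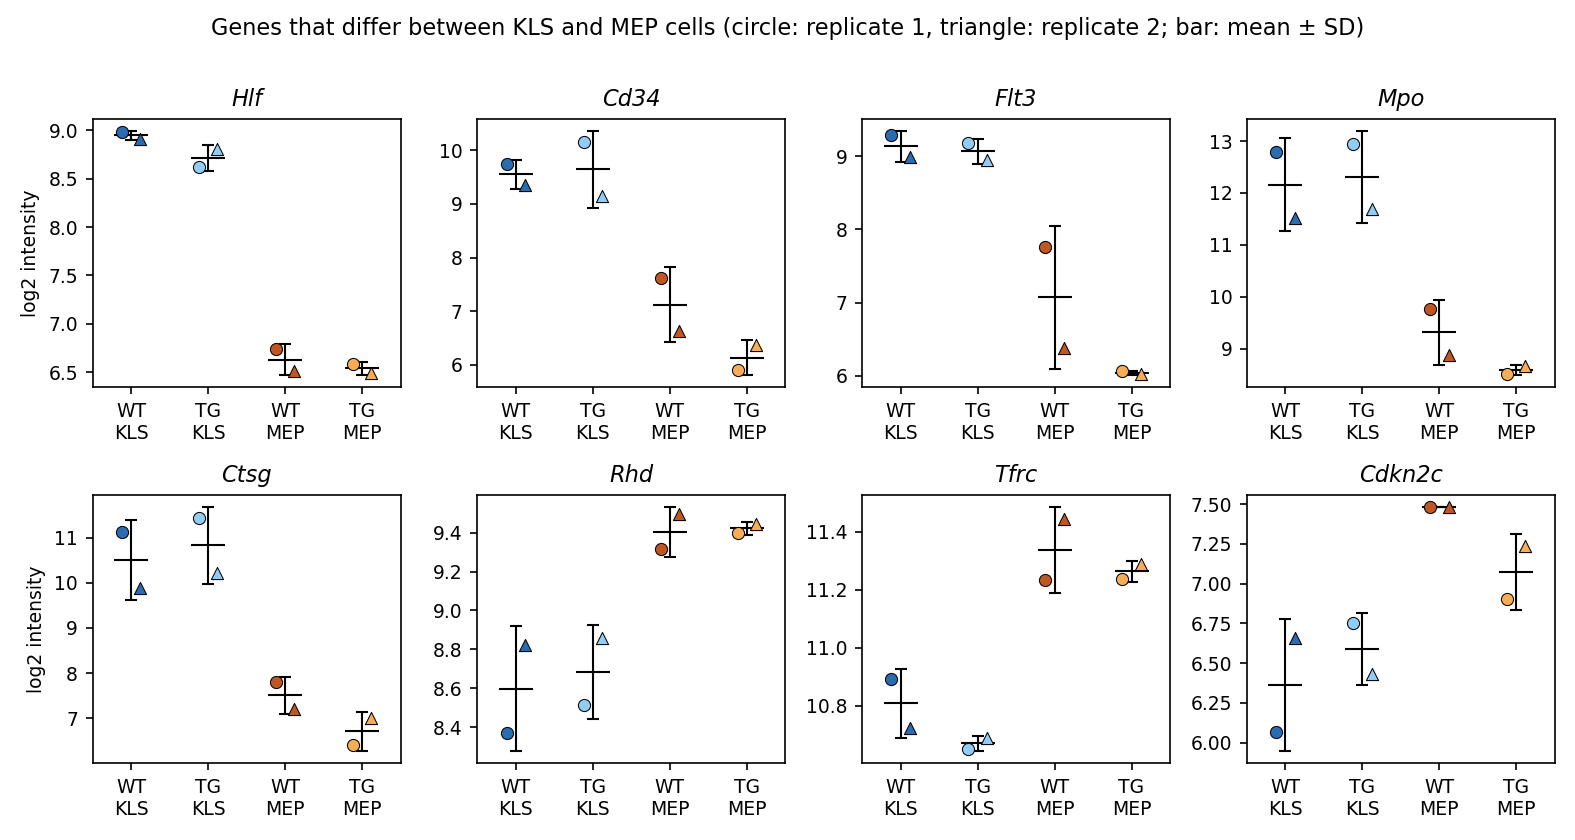
Log2 intensity (vertical axis) of 8 genes on each array of WT and TG KLS and MEP cells (circle: replicate 1; triangle: replicate 2; bar: mean ± SD of 2 arrays). Hlf averages 8.83 in KLS and 6.59 in MEP cells, and Rhd 8.64 and 9.41.

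Between the cell types 14 gene lists passed the camera threshold, 12 higher in KLS and 2 higher in MEP cells. The granulocyte and monocyte list was higher in KLS cells by a mean log2 difference of 1.31, with 10 of 26 members past the threshold over all genes and 25 adjusted over the list alone. Its 12 mature neutrophil genes, grouped after their values were seen, were higher in KLS cells by 0.97 (95% interval 0.14 to 1.81). Another 22 neutrophil genes, in none of the fixed lists, were higher by 0.83 (0.11 to 1.55). With 1 array left out, the mean of the 12 ran from 0.76 without WT MEP 2 to 1.19 without WT MEP 1. That of the 22 ran from 0.65 without WT KLS 2 to 1.02 without WT KLS 1. For both sets the interval then included 0, except without WT KLS 1 or WT MEP 1. For the granulocyte and monocyte list and for the HSC, Hox, erythroid and cell cycle lists, adjusted p = 0.0784 with an estimated correlation. The HSC and multipotent progenitor list was higher by 0.68, with 8 of 27 members higher over all genes, and 10 higher and 1 lower adjusted over the list alone. Hox genes and cofactors were higher by 0.27 (2 of 19 members over all genes, 4 adjusted over the list alone), among them Hoxa5 at 0.75 ± 0.13, which did not pass with median centring (adjusted p = 0.0601) or without TG KLS 1, TG MEP 1, TG MEP 2, WT KLS 1, WT KLS 2 or WT MEP 2 (up to 0.141). The erythroid list was lower in KLS cells, at -0.40, with 2 of 35 members over all genes and 22 adjusted over the list alone. The cell cycle list was also lower, at -0.26, with 0 of 43 members over all genes and 11 adjusted over the list alone.

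Mast cell, basophil and eosinophil genes were higher in KLS cells by 0.53 (3 of 13 members over all genes, 7 adjusted over the list alone), with the basophil protease Mcpt8 at 1.68 ± 0.18, and for this list and the stromal list adjusted p = 0.0915 with an estimated correlation. Stromal and endothelial genes were higher by 0.46 (3 of 15, 6 adjusted over the list alone), with the endothelial sialomucin Emcn at 1.24 ± 0.13. Cytokine receptors were higher by 0.54 (3 of 17, 7 adjusted over the list alone), with the G-CSF receptor Csf3r at 1.16 ± 0.16, and megakaryocyte genes by 0.35 (1 of 20, 6 adjusted over the list alone), and for both adjusted p = 0.142 with an estimated correlation. Immediate early and heat shock genes were higher by 0.39 (0 of 24, 5 adjusted over the list alone; adjusted p = 0.195 with an estimated correlation). TGF-beta and mesenchymal genes were higher by 0.23 (0 of 22, 0 adjusted over the list alone; adjusted p = 0.321 with an estimated correlation). Interferon response genes were higher by 0.26 (2 of 32, 7 adjusted over the list alone), with the immunoproteasome subunit Psmb8 at 1.13 ± 0.19, and for the list adjusted p = 0.429 with an estimated correlation. Lymphoid genes were higher by 0.48 (3 of 24, 4 adjusted over the list alone), and adjusted p = 0.455 with an estimated correlation. JAK-STAT genes were higher by 0.12 (0 of 25, 1 adjusted over the list alone), and adjusted p = 0.510 with an estimated correlation. Psmb8 did not pass as deposited (adjusted p = 0.0560), with median centring (0.0873), or without TG KLS 1, TG MEP 1, TG MEP 2, WT KLS 1, WT KLS 2 or WT MEP 2 (from 0.0584 to 0.143). Without TG MEP 1 and without TG MEP 2, adjusted p was 0.0629 and 0.0516 for Mcpt8, 0.0629 and 0.0518 for Emcn, and 0.0686 and 0.0837 for Csf3r, which also missed the threshold without TG KLS 1 (0.0874).

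The lists not called were globin (-0.09), CDK inhibitor (-0.13), p53 target (-0.0010), IGF and PI3K-AKT (0.09), let-7 and Lin28 (0.10), Polycomb (-0.01) and ribosomal protein genes (0.02). Of their members 1 passed over all genes and 1 adjusted over the list alone, in both cases Cdkn2c. The lymphoid mean was 0.87 without WT MEP 1 and 0.098 without WT MEP 2, where it was not called (adjusted p = 0.964). Without WT MEP 2 the interferon (0.17) and TGF-beta lists (0.15) were not called either (adjusted p = 0.0622 each). The JAK-STAT call was lost without TG KLS 1, TG MEP 1, WT KLS 1 or WT MEP 2 (adjusted p = 0.0874, 0.0952, 0.173 and 0.608), with means of 0.070, 0.098, 0.080 and 0.053, and the mean was 0.19 without WT MEP 1 and 0.073, still called, with median centring.

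On the WT MEP 1 array, 3 genes of early progenitors, picked after their values were seen, stood above the other MEP arrays. Meis1, a homeobox gene of stem cells, was at 8.10 there and at 6.13 on WT MEP 2, Flt3 at 7.76 and 6.38, and Cd34 at 7.62 and 6.63, while Hlf was at 6.74 and 6.52. In TG MEP cells Meis1 was at 6.53 ± 0.19, Flt3 at 6.04 ± 0.03 and Cd34 at 6.14 ± 0.33 (SD, n = 2 each).

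The genotype comparison in KLS cells concerns the stem and progenitor fraction. Lymphoid genes were lower in TG KLS cells as a list, at a mean of -0.27, with 23 of 24 members below 0 and 0 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.0388, and adjusted p = 0.955 with an estimated correlation). Its member with the smallest p was Ccr9, a chemokine receptor of lymphocytes, at -0.58 ± 0.18, not past the threshold. Outside the lists, the immunoglobulin segment Igkv8-30 was at 5.51 ± 0.22 in TG and 6.76 ± 0.13 in WT cells (n = 2 each), and the mitochondrial carrier Slc25a21 at 7.95 ± 0.18 and 7.19 ± 0.07, neither past the threshold. By limma 0 genes passed, with 500 at an unadjusted p under 0.05 where chance gives about 997. With the 4 KLS arrays alone 0 passed (474 unadjusted), as with ordinary least squares (662 unadjusted). The lymphoid call was lost without TG KLS 1, TG KLS 2, WT KLS 1 or WT KLS 2 (adjusted p = 0.114, 0.0655, 0.304 and 0.101), with means of -0.36, -0.19, -0.17 and -0.38. Erythroid genes were called as lower without TG KLS 2 (-0.20) or WT KLS 1 (-0.24), and without TG KLS 1 granulocyte and monocyte genes (-0.32) were called as lower and immediate early genes (0.18) as higher. Median centring added calls of cell cycle (0.11) and ribosomal protein genes (0.09) as higher in TG KLS cells (adjusted p = 0.0422 each). With these arrays left out or this scaling, adjusted p was at least 0.938 for each list with an estimated correlation. The other 20 lists had means from -0.12 to 0.13 and were not called. Of these, the megakaryocyte, cell cycle, interferon and TGF-beta lists had a mean, median and test that differed in sign.

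In MEP cells the genotype comparison concerns erythroid and megakaryocyte progenitors. Granulocyte and monocyte genes were lower in TG MEP cells as a list, at a mean of -0.80, with 25 of 26 members below 0. Of these, 0 passed over all genes and 12 adjusted over the list alone, including Cybb, a subunit of the NADPH oxidase of phagocytes. It was at 7.80 ± 0.20 in TG and 9.34 ± 0.76 in WT MEP cells (n = 2 each), a change of -1.53 ± 0.33. The list passed camera (adjusted p = 3.37e-18, and adjusted p = 0.489 with an estimated correlation), and without WT MEP 1 its mean was -0.50 (95% interval -1.29 to 0.30), still called (adjusted p = 4.84e-09, and adjusted p = 0.827 with an estimated correlation). Over 12 mature neutrophil genes of this list, grouped after their values were seen, the mean log2 level was 10.23 on WT MEP 1, 9.37 on WT MEP 2, 8.51 on TG MEP 1 and 8.65 on TG MEP 2.

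Lymphoid genes were also lower in TG MEP cells as a list, at -0.90 (adjusted p = 0.489 with an estimated correlation), with 0 of 24 members past the threshold over all genes. Cd3d, a chain of the T-cell receptor complex, at -0.85 ± 0.19, was the 1 member that passed adjusted over the list alone. Without WT MEP 1 the lymphoid mean was -0.13 and not called (adjusted p = 0.354), and without WT MEP 2 it was -1.67. On WT MEP 1 the lymphoid list averaged 8.07, against 6.53 on WT MEP 2, 6.34 and 6.46 on the TG MEP arrays and 7.12 to 7.58 on the KLS arrays. Erythroid genes had a mean of -0.14 and were not called (adjusted p = 0.0968), with 0 of 35 members past the threshold over all genes and 2 adjusted over the list alone. These were Alas2, which starts haem synthesis in red cells, at -1.20 ± 0.24, and the red cell anion exchanger Slc4a1 at -1.46 ± 0.35, which was chosen after its values were seen. The erythroid mean was -0.22 without WT MEP 1, where it was called (adjusted p = 0.00857, and adjusted p = 0.827 with an estimated correlation), and -0.068 without WT MEP 2, where it was not (adjusted p = 0.854). With the values as deposited its mean was -0.22, and with median centring -0.24, and both were called (adjusted p = 8.99e-05 and 8.13e-05), while for every list under these scalings adjusted p was at least 0.314 with an estimated correlation. It was also called without WT KLS 1 or WT KLS 2 (adjusted p = 0.0479 each, and adjusted p = 0.578 with an estimated correlation). Xpo7, a nuclear transport receptor, was at -1.44 ± 0.24 and did not pass.

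Cytokine receptors (-0.38), mast cell, basophil and eosinophil genes (-0.29), p53 targets (-0.29), JAK-STAT genes (-0.25) and TGF-beta and mesenchymal genes (-0.23) were lower in TG MEP cells as lists, and for each adjusted p = 0.489 with an estimated correlation. Of their members 0 passed over all genes. Adjusted over the list alone 1 passed, Bcl2l1 of the JAK-STAT list, which encodes the survival protein Bcl-xL, at -1.11 ± 0.23. Without WT MEP 1 none of these 5 lists was called (adjusted p = 0.244, 0.427, 0.312, 0.318 and 0.874), with means of -0.16, -0.11, -0.13, -0.11 and -0.067, while without WT MEP 2 the means were -0.59, -0.48, -0.45, -0.38 and -0.40. Without TG MEP 1 the p53 (-0.19) and TGF-beta lists (-0.18) were not called (adjusted p = 0.0778 and 0.0750). Of the lists not called on all arrays, interferon response genes took opposite signs, called as higher without WT MEP 1 (0.04) and as lower without WT MEP 2 (-0.34) or TG MEP 2 (-0.25). Immediate early and heat shock genes were called as higher without WT MEP 1 (0.14) or TG MEP 1 (0.17). HSC and multipotent progenitor (-0.47), megakaryocyte (-0.38) and IGF and PI3K-AKT genes (-0.22) were called as lower without WT MEP 2. As deposited, cell cycle (-0.079), IGF and PI3K-AKT (-0.15), interferon (-0.16), Polycomb (-0.13), megakaryocyte (-0.20) and HSC and multipotent progenitor genes (-0.21) were called as lower, and with median centring all of these but the last (cell cycle -0.11, Polycomb -0.16). With these arrays left out or these scalings, adjusted p was at least 0.186 for every list with an estimated correlation. The 14 lists not called had means from -0.24 to 0.04, and among them let-7 and Lin28 genes (-0.02) and immediate early genes (-0.03) had a test of the other sign.

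By limma 0 genes passed in MEP cells, with 739 at an unadjusted p under 0.05, 247 higher and 492 lower in TG. With the 4 MEP arrays alone 0 passed (702 unadjusted), as with ordinary least squares (555 unadjusted). Without WT MEP 2, when WT MEP 1 was the only WT MEP array, 144 genes were called, all lower in TG, among them Cybb (adjusted p = 0.0236), Flt3 (0.0160), Bcl2l1 (0.0297) and the p53 target Btg2 (0.0277).

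**Figure D2:**
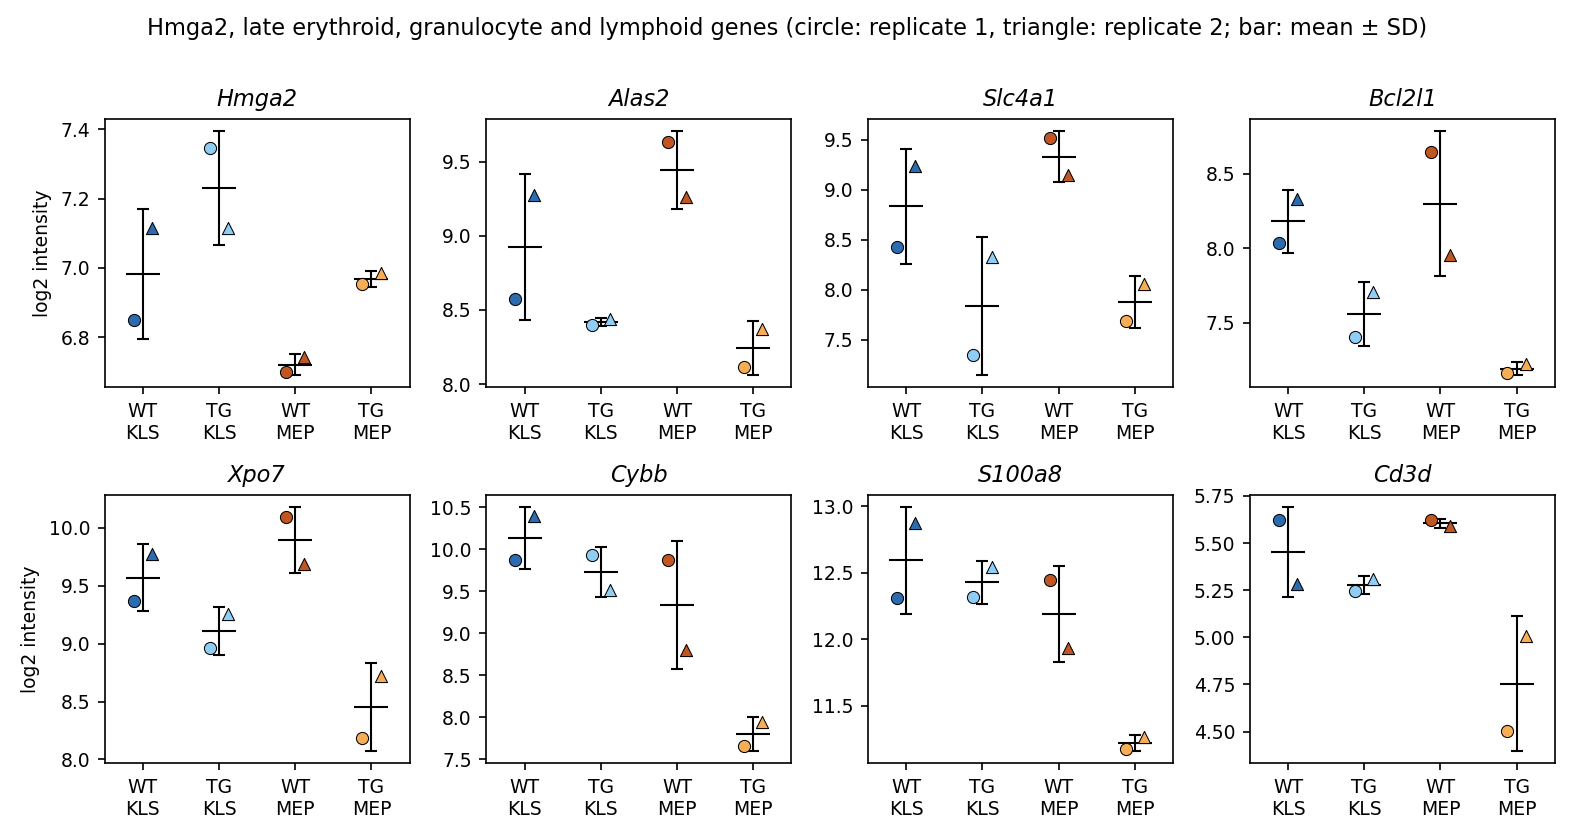
Log2 intensity (vertical axis) of 8 genes on each array of WT and TG KLS and MEP cells (circle: replicate 1; triangle: replicate 2; bar: mean ± SD of 2 arrays). Hmga2 averages 6.97 in TG and 6.72 in WT MEP cells, and Cybb 7.80 and 9.34.

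**Figure D3:**
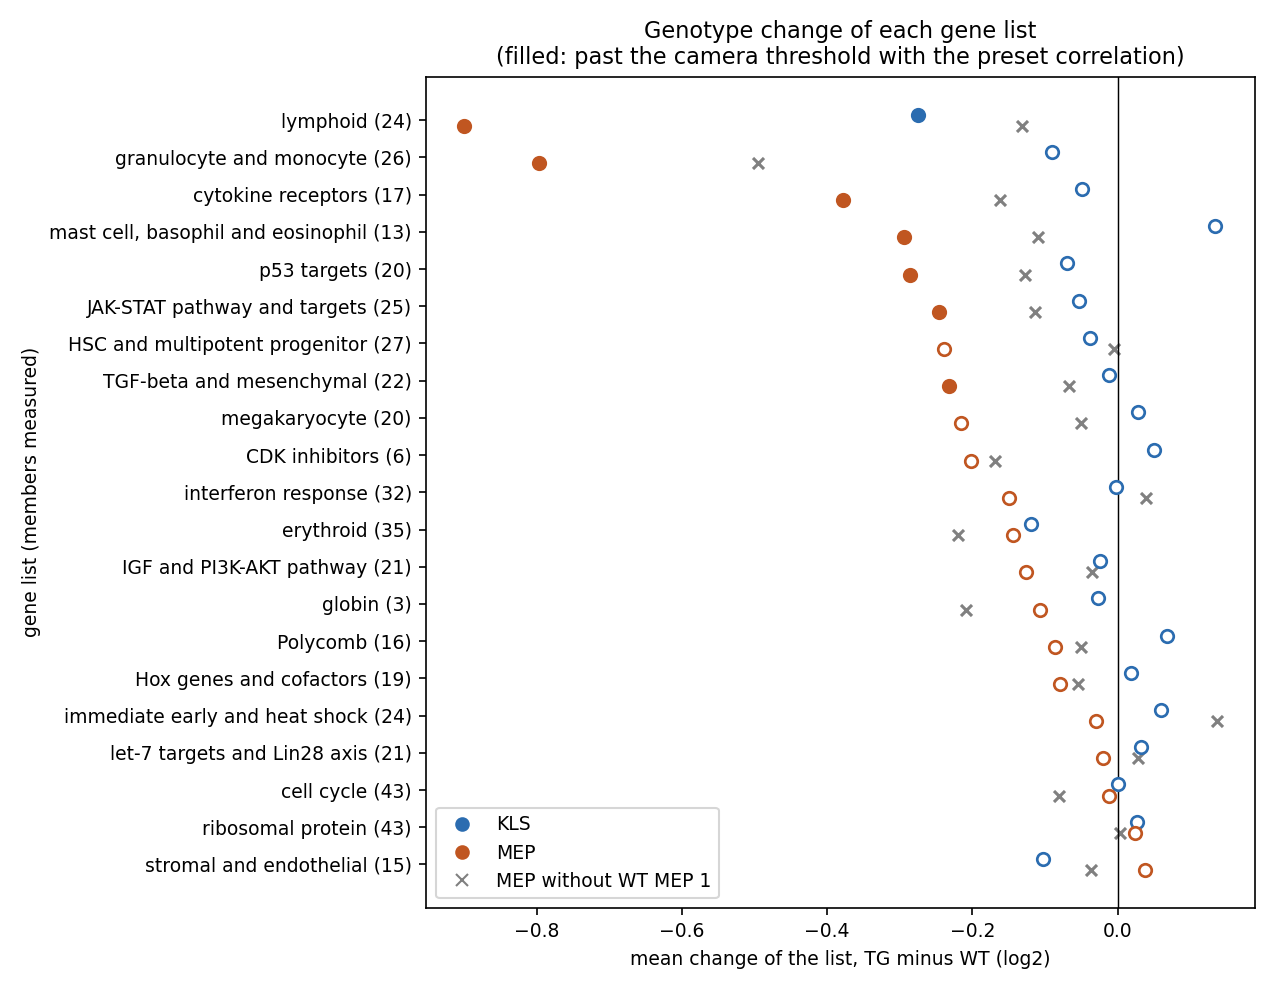
Mean log2 change (horizontal axis, TG minus WT) of each gene list in KLS (blue) and MEP cells (orange), filled where past the camera threshold with the preset correlation. Grey crosses show MEP cells without WT MEP 1, where the lymphoid mean is -0.13 against -0.90 with it.

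Averaged over both cell types, the granulocyte and monocyte list was lower in TG cells at -0.44, with 0 of 26 members past the threshold over all genes and 6 adjusted over the list alone. For this list and the lymphoid, erythroid, cytokine receptor, p53 and JAK-STAT lists, adjusted p = 0.718 with an estimated correlation. Lymphoid genes were lower at -0.59, with 24 of 24 members below 0 and 0 passing over all genes or adjusted over the list alone. Erythroid genes were lower at -0.13, with 25 of 35 members below 0, 0 passing over all genes and 2 adjusted over the list alone, Alas2 at -0.85 ± 0.17 and, chosen after its values were seen, Slc4a1 at -1.23 ± 0.25. Cytokine receptors (-0.21), p53 targets (-0.18) and JAK-STAT genes (-0.15) were lower as well, with 0 members past the threshold over all genes. Bcl2l1 of the JAK-STAT list, at -0.87 ± 0.16, was the 1 of these that passed adjusted over the list alone. As in MEP cells, this 1 member does not stand for JAK-STAT signalling.

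By limma 0 genes passed over both cell types, with 649 at an unadjusted p under 0.05, 237 higher and 412 lower in TG. The genes with the smallest p included Rnu3a, a small nucleolar RNA, at -1.28 ± 0.22, Xpo7 at -0.95 ± 0.17 and the Y-linked gene Uty at 0.45 ± 0.11. Without WT MEP 2, 67 genes were called, all lower in TG. The erythroid call was lost without TG KLS 1, WT KLS 2 or WT MEP 2 (adjusted p = 0.481, 0.435 and 0.309), with means of -0.088, -0.071 and -0.093. The cytokine receptor call was lost without TG KLS 2, WT KLS 1 or WT MEP 1 (means of -0.15, -0.12 and -0.11, adjusted p = 0.0765, 0.273 and 0.194), and without WT MEP 2 its mean was -0.32. The JAK-STAT call was lost without the same arrays (means of -0.10, -0.11 and -0.083), with adjusted p = 0.198 without WT KLS 1 and 0.237 without WT MEP 1. The p53 call was lost without TG KLS 2, TG MEP 1, WT KLS 1 or WT MEP 1 (adjusted p = 0.0644, 0.166, 0.141 and 0.216), with a mean of -0.098 without WT MEP 1. Without WT MEP 1 the granulocyte mean was -0.29 and the lymphoid mean -0.20, both still called, and immediate early genes were called at 0.10 (adjusted p = 0.0342, and adjusted p = 0.841 with an estimated correlation). These were also called without TG MEP 1 (0.11), and ribosomal protein genes without WT KLS 2 (0.04), with adjusted p = 0.805 and 0.846 with an estimated correlation. Without WT MEP 2 the lymphoid mean was -0.97, and HSC and multipotent progenitor (-0.25), megakaryocyte (-0.18), mast cell (-0.17), IGF and PI3K-AKT (-0.12), interferon (-0.17) and TGF-beta genes (-0.20) were called as lower, for each of which adjusted p = 0.392 with an estimated correlation. The 15 lists not called had means from -0.14 to 0.03, of which HSC and multipotent progenitor genes (-0.12) were called as deposited (adjusted p = 0.0449), where adjusted p was at least 0.463 for every list with an estimated correlation. Of these, the cell cycle and Polycomb lists had a mean, median or test that differed in sign.

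The interaction tests whether the genotype change differs between the cell types. The change of the granulocyte and monocyte list was higher in KLS than in MEP cells by 0.71, with S100a8, a calcium-binding protein of neutrophils, at 0.80 ± 0.32. For this and the mast cell list adjusted p = 0.665 with an estimated correlation. The mast cell, basophil and eosinophil list differed by 0.43, with the eosinophil granule protein Prg2 at 1.31 ± 0.40. The lymphoid list differed by 0.63, with Cd3d at 0.68 ± 0.27 (adjusted p = 0.673 with an estimated correlation). In each list 0 members passed over all genes and 0 adjusted over the list alone. Without WT MEP 1 the granulocyte difference was 0.40 and called, the mast cell difference was 0.24 and not called (adjusted p = 0.149), and the lymphoid difference was -0.14 and called in the other direction (adjusted p = 0.0209), and for all of them adjusted p = 0.965 with an estimated correlation. Without WT MEP 2, HSC and multipotent progenitor (0.43), megakaryocyte (0.41), p53 (0.38), JAK-STAT (0.33), cytokine receptor (0.54), interferon (0.34) and TGF-beta genes (0.39) were called as well. Cytokine receptors were also called without TG KLS 2 (0.47), TG MEP 1 (0.31) or WT KLS 1 (0.51), and JAK-STAT genes without TG KLS 2 (0.29) or WT KLS 1 (0.27). TGF-beta (0.35) and stromal genes (-0.16) were called without TG KLS 2, p53 (0.31) and interferon genes (0.25) without TG MEP 2, and interferon (0.20) and CDK inhibitor genes (0.39) without WT KLS 2. As deposited and with median centring, calls were added for cell cycle (0.15 and 0.21, against 0.01), erythroid (0.16 and 0.21, against 0.02), Polycomb (0.24 and 0.29, against 0.15), JAK-STAT (0.24 and 0.30), cytokine receptor (0.37 and 0.42), interferon (0.18 and 0.23) and stromal genes (-0.24 and -0.19), and as deposited for TGF-beta genes (0.24). An intensity trend also added JAK-STAT, cytokine receptor and TGF-beta genes (adjusted p = 0.0489, 0.0438 and 0.0489), and array weights the latter pair (0.0426 and 0.0472). With these arrays left out or these scalings, adjusted p was at least 0.227 for every list with an estimated correlation. The lymphoid difference was 1.39 without WT MEP 2, and with the dimmest 30% of genes left out it was not called (adjusted p = 0.118). By limma 0 genes passed, with 453 at an unadjusted p under 0.05, and 10 passed without WT MEP 2, all with a change higher in KLS than in MEP cells. The other 18 lists had means from -0.14 to 0.33, and the erythroid and globin lists had a mean that differed in sign from the median.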

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

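The tests of normalization, of the WT MEP 1 array alone and of KLS cells in that preparation were chosen after the results were seen. By the test of the difference itself, the genotype change differed between KLS and MEP cells for the granulocyte and monocyte list (0.71), the lymphoid list (0.63) and the mast cell, basophil and eosinophil list (0.43). With an estimated correlation 0 of these calls held. The same was true of the 14 lists called between KLS and MEP cells, so losing a call there does not show that a difference is absent. The differences without WT MEP 1 were 0.40 (called), -0.14 (called in the other direction, adjusted p = 0.0209) and 0.24 (not called, adjusted p = 0.149), each with adjusted p = 0.965 with an estimated correlation, and without WT MEP 2 the lymphoid difference was 1.39.

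Granulocyte genes were lower in TG MEP than in WT MEP arrays. Without WT MEP 1 the list had a mean of -0.50 and still passed camera (adjusted p = 4.84e-09, and adjusted p = 0.827 with an estimated correlation), but the 95% interval from -1.29 to 0.30 includes 0 and so leaves open whether that array is the whole cause. A candidate explanation is more neutrophil RNA in the WT MEP preparations, whose sorting gate is not given in the sources used here. The 22 neutrophil genes written down before their values were seen, 0 of them in the fixed lists, had a mean of -0.73 (95% interval -1.74 to 0.29), or -0.42 without WT MEP 1 and -1.04 without WT MEP 2, with 22 of 22 below 0 and the 2 with the brightest probe sets, Wfdc21 and Lcn2 (mean log2 intensities 9.57 and 8.90), at -0.70 and -1.53. S100a8 of the fixed list averaged 12.19 in WT and 11.22 in TG MEP cells; the intervals leave this open, and an effect of the genotype in MEP cells stays open too, untested.

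Late erythroid genes were lower in TG than in WT arrays, at a mean of -0.84 over 7 genes picked for this pattern. Their mean was -0.56 in KLS cells (95% interval -1.26 to 0.14) and -1.12 in MEP cells (-1.82 to -0.42). Since the 7 genes were picked for being lower in TG, these intervals do not test the fall. Over 9 early erythroid genes of the fixed lists the mean over both cell types was -0.02 (95% interval -0.16 to 0.13). The contrast of the 7 genes with these 9 is partly built in by the same choice. Under both other scalings the mean of the 7 genes was at least as far below 0 (-0.84). The deposited medians spanned 0.106, so median centring could hardly have removed a change of this size, and its result decides nothing about normalization. All of these scalings start from the deposited values, so an effect of processing before deposit could not be tested. Less RNA carried over from maturing red cells in the TG preparations may play a part, in cells sorted by flow with gates not given in the sources used here. The 18 measured reticulocyte genes written down before their values were seen, 0 of them in the fixed lists, had a mean of -0.26 (95% interval -0.54 to 0.01). With 1 array left out it ran from -0.35 without WT KLS 1 to -0.18 without WT KLS 2. Of these genes 17 of 18 were below 0. The 2 with the brightest probe sets, Bnip3l and Mkrn1 (mean log2 intensities 10.88 and 9.45), were at -0.070 and -0.35. These values leave the carried-over RNA open. An effect of the genotype on late erythroid genes stays open as well, untested.

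The HSC and multipotent progenitor list averaged 6.90 on WT MEP 1 and 6.38 to 6.48 on the other MEP arrays, and with it moved the lymphoid list (8.07, against 6.34 to 6.53, and 7.12 to 7.58 on the KLS arrays) and the granulocyte and monocyte list (8.52, against 7.33 to 7.91). KLS cells in that preparation would raise all abundant KLS transcripts by a like share. The 583 genes called higher in KLS cells without that array implied a median share of 68.8% and the 10 among them from the stem cell list 42.6%, but 6 granulocyte progenitor genes implied a median of 6.33%, with Irf8 apart from the others at 76.6%, and Hlf 3.98%, which argues against KLS cells as a whole as the only source. The quartiles over all these genes were 43.1% and 105%, and members of the stem cell list ran from 2.76% (Mecom) to 170% (Mmrn1). Shares larger than the whole are not what a mixture with KLS cells alone gives, though error in this 1 array or in the KLS means could raise them. Hlf was named for this test after the results were seen. The other MEP arrays that served as the baseline are of both genotypes, so a genotype change would shift the shares. Other cells or another change in this preparation stay open, and no biological explanation was tested, since the pattern lies in 1 array.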

How the results depend on the processing

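The crossed replicate block and the estimated correlation with an array left out or another scaling were chosen after the data were seen. Gene counts of 0 by genotype stayed at 0 in KLS cells under all alternatives; in MEP cells, over both and for the interaction the exceptions are given here. With each array left out in turn, where a lone array is assumed to vary like the other groups, genes called ran from 0 to 0 in KLS, 0 to 144 in MEP, 0 to 67 over both, 0 to 10 for the interaction and 1 to 738 between cell types. Lists called ran from 0 to 2, 4 to 11, 3 to 11, 2 to 10 and 10 to 14 in the same order. Between cell types 123 genes were called with median centring, 151 with a 2-fold minimum, 780 at an adjusted p under 0.10 and 1 (Hlf) with all probe sets singly, where the prior degrees of freedom were 2.49. Genotype lists in MEP numbered 14 as deposited and 13 with median centring, those in KLS 3 with median centring, and interaction lists 11 as deposited, 10 with median centring, 6 with an intensity trend and 5 with array weights. With an estimated correlation 0 lists were called in each contrast, also with any array left out, as deposited or with median centring, and with fry 0 by genotype or interaction and 8 between cell types. With the replicate number as a block, 1 gene was called by genotype over both (Rnu3a), 562 genes between cell types and 6 interaction lists. It added the HSC list by genotype in MEP and over both (adjusted p = 0.0237 and 0.0319), the megakaryocyte list in MEP (0.0420), and the JAK-STAT, cytokine receptor and TGF-beta lists in the interaction (0.0492, 0.0120 and 0.0411). Deviations of arrays with the same number correlated from -0.28 to 0.38 across genes. They were positive among TG KLS, WT KLS and WT MEP (0.18 to 0.38) and negative for each of these with TG MEP (-0.28 to -0.17). The numbers are therefore not shown to pair the arrays. The crossed replicate block, with the numbers of the TG MEP arrays exchanged, gave 1040 genes between cell types and 0 by genotype or interaction. Signs turned for Hbb-bh1 by genotype in MEP (0.0029 as deposited), the Hmga2 interaction (0.036 as deposited, 0.093 with median centring, -0.13 to 0.13 with arrays left out), Cdkn2c by genotype in KLS (-0.066 to 0.52 with arrays left out), and the lymphoid list in the interaction (-0.14 to 1.39) and, by its test, between cell types (0.098 to 0.87). Of named genes, 1284 values under other settings kept their direction and side of the threshold, 25 lost the call, 9 gained it and 3 turned sign; with arrays left out these were 1170, 164, 13 and 5. Genes named by genotype or interaction had no call on all arrays to lose, which raises the number kept. For lists called on all arrays, 224 values under other settings kept the call and 117 lost it, those with an estimated correlation included. The cause of these changes was not tested. Robust variances were not run for lists, and pseudocounts do not apply to log2 values. Signal over background could not be read from these values.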

Other observations

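The splits of the arrays were planned before their results were seen, and the sex-linked genes and the grouping of neutrophil genes were chosen afterwards. Genes of mature neutrophils were bright in the KLS fraction, whose gate by name leaves out lineage-positive cells. The mean log2 level of 12 such genes was 9.90 and 10.71 on the WT KLS arrays and 10.11 and 9.94 on the TG KLS arrays.

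Of 4 sex-linked genes, 0 passed limma's threshold by genotype over both cell types (adjusted p = 0.999 each). Xist, transcribed from the inactive X chromosome, had a log2 change of -0.51 ± 0.16 over both cell types, and the Y-linked genes Eif2s3y and Kdm5d had changes of 0.46 ± 0.13 and 0.25 ± 0.11, with TG and WT arrays overlapping for Kdm5d in MEP cells. Over the 8 arrays Xist ran from 9.47 to 10.67 and Eif2s3y from 7.54 to 8.65. Uty, also Y-linked, was at 0.45 ± 0.11. Xist was thus lower and these Y-linked genes higher in TG. That 0 passed does not show pools alike in sex, since 0 of all genes passed in this contrast. The sex of the pooled mice is not given in the sources used here. A difference in sex between TG and WT pools is not excluded and could not be told apart from the genotype.

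The 8 arrays were also split into other groups of 4, with the other factor as a term, which gave 34 splits with the real one. Between KLS and MEP cells the real split called 444 genes and the highest of the others 1, so 1 of 34 splits gave as many. No smaller share is possible with 34 splits. The other splits mix KLS and MEP arrays, so the cell type difference adds to their spread and keeps their calls low. The comparison therefore cannot exclude chance by itself. By genotype over both cell types the real split called 0 genes and the highest of the others 1, and since no split can give fewer than 0, that all 34 gave as many says nothing about chance. At an unadjusted p under 0.05 the real split gave 716 genes, 13 of 34 splits gave as many, and chance cannot be excluded. The highest of the others, with 2952 genes, set TG KLS 1, WT KLS 1, WT MEP 1 and TG MEP 2 against the rest. It called 0 genes after adjustment and was picked as the largest. The same grouping is the crossed replicate block, which was chosen after the data were seen. With that block as a term, 1040 genes were called between cell types, against 319 without it, and 0 by genotype. What such a structure of the arrays reflects stays open, untested.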
